A study of Mus musculus with 13 samples.

How the data were processed

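Gene counts of 13 mouse RNA libraries were re-analysed: mouse embryonic fibroblasts (MEF) with a Cre-inducible copy of Foxn1, cultures at day 2 and day 10 after a Cre plasmid was delivered by nucleofection, cells of day 12 sorted by Epcam, and fetal thymic epithelial cells (TEC). The columns named for cultures without Cre were taken as the MEF group, the only group that this name can mean among the labels. Per the labels' protocols, cells were sorted and RNA was taken with spin columns and treated with DNase. The same protocol text stands under every sample, fetal TEC included, so which steps fetal TEC went through is not given in the sources used here.

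The values are raw counts per gene symbol, as deposited by the authors, with no scaling. FastQC, Trimmomatic, HISAT2, SAMtools, StringTie and DESeq2 are named per the submitters' processing notes, as is the mm10 build, without versions, order or settings. How reads shared by near-identical genes were assigned, and whether strand was used, is not given there. Genes with close copies, such as the class II and Ccl21 families, and genes that overlap on either strand are therefore uncertain as single genes. Ensembl transcript lengths and gene positions came from GENCODE release M21 on the same build, for 95.7% of symbols. No special lines for unassigned reads were found among the 24394 symbols, and 4044 of these were at 0 in every library.

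Counts were tested in R 4.3.3 with edgeR 4.0.16: TMM scaling (factors 0.71 to 1.16), filterByExpr by group (17004 genes tested), and 1 robust quasi-likelihood fit of all libraries with 1 mean per group (common dispersion 0.296). Each of the 8 comparisons was an F test between the means of its groups, with Benjamini-Hochberg adjustment and calls at an adjusted p under 0.05, without a fold minimum. All groups share 1 estimate of the spread, so the wide Epcam-positive pair lowers the counts of calls elsewhere. CPM of genes were computed with the TMM factors, and the sums of lists, the sex-linked and the Gapdh values of single libraries by library size alone, except where TMM factors are named. The standard error was taken from the fold change and its F value. Libraries held 35805780 to 86465460 counts, so the floor of 3 counts in 1 library, with its TMM factor, lies at 0.0300 to 0.0776 CPM. Genes at 0 in a group have a lower bound from 3 counts over that group, and genes with 1 to 3 counts a ratio with a 95% counting interval.

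Gene lists (30, of which 29 had at least 3 tested genes) and the rule for named genes were fixed before the data were examined, as were the comparisons, the tests and the alternatives except those said to be later. Lists were tested with camera of limma 3.58.1 on the edgeR fit (preset correlation 0.01, adjusted over the lists within a comparison), and again with an estimated correlation and with fry. The lists hold TEC genes, epithelial, mesenchymal, signalling, immune and growth genes, and markers of other cell types. Named genes are the largest rises and falls (up to 8 each, at least 5 CPM in the higher group, no overlap of samples, left out only from the smallest up), up to 4 members of each list described with the smallest p, and 16 genes named in every comparison.

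Alternatives were DESeq2 1.42.0 size factors, library size alone, no filter and a stricter filter, the DESeq2 Wald test, a fit of only the groups compared, a fold minimum by glmTreat, replicate number as a block, and each library left out. The 3 later alternatives are described with their effect in the closing part. Replicate numbers were not used as pairs, since no label says that a number marks a shared culture or day. Splits of samples were not counted because no comparison has 3 libraries in both groups. Other work used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

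The steps were tested on simulated data for each comparison, with 100 genes changed 4-fold and 100 changed 16-fold. In the order day 2 against MEF, day 10 against MEF, day 10 against day 2, Epcam-positive against Epcam-negative, Epcam-positive against MEF, Epcam-negative against MEF, fetal TEC against MEF and Epcam-positive against fetal TEC, the share called was 7, 7, 13, 7, 8, 5, 7 and 10% at 4-fold. At 16-fold it was 54, 69, 73, 58, 57, 61, 71 and 62%, so most 4-fold changes would be missed. At least 95% of signs were right and at most 5.7% of calls false, in simulation only. A 4-fold rise planted in the interferon list at day 2 gave adjusted p = 7.48e-46, with 0 of the 28 other lists called by camera.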

Results

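Mouse embryonic fibroblasts (MEF) that carry a Cre-inducible copy of Foxn1, the transcription factor that thymic epithelial cells (TEC) need to form, were compared with their induced derivatives (iTEC) and with TEC of the fetal thymus. The 13 RNA libraries fall into 6 groups: MEF from E13.5 embryos (n = 2), iTEC at day 2 (n = 2) and day 10 (n = 3) after Cre, iTEC at day 12 sorted as Epcam-negative (n = 2) or Epcam-positive (n = 2), and fetal TEC from E15.5 (n = 2). Each library held 35805780 to 86465460 counts, and 17004 of the 24394 genes were tested. Nothing in the labels says that replicates came from separate cultures or animals, so the p-values may measure technical spread only. Gene levels are CPM, counts scaled by library size and TMM factor, as mean ± SD. Log2 changes (log2) are given ± standard error from edgeR, p-values are adjusted over all tested genes, and the n of each comparison is that of its groups. Counts over a list alone, with p-values adjusted within the list, are given where they differ. Lower bounds stand for genes with no count in 1 group (3 counts over that group), and these bounds and the counting intervals cover counting error only. Without 1 library of the group at 0, bounds are lower through the floor alone, 2.45- and 1.69-fold for MEF replicates 1 and 2 and 1.37- to 3.23-fold for other libraries. Named genes had no overlap between the samples of both groups where a change is stated as called, unless said otherwise.

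On mm10, with chromosome, start and end in brackets, the genes whose levels are given for every group are Foxn1 (11, 78357577 to 78386558), Epcam (17, 87635979 to 87651129), Dll4 (2, 119325784 to 119335962), Ccl25 (8, 4325210 to 4360020), Psmb11 (14, 54621433 to 54629556), Prss16 (13, 22002173 to 22009742) and Krt8 (15, 101996698 to 102004482). The counts of Foxn1 do not part the induced copy from the endogenous gene.

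Some libraries stand apart for reasons other than their group. Epcam-positive replicate 2 and both fetal TEC libraries lacked reads of long transcripts: counts fell with transcript length across genes (rho -0.555 to -0.441, against -0.137 to 0.318 in the other 10 libraries). The ribosomal RNA gene Rn45s took 0.036 to 0.079% of the counts of these 3 libraries, and elsewhere 0.268 to 3.62%. Across genes, the rank correlation of the Epcam-positive pair was 0.757, against 0.967 and 0.968 for replicate 1 with the Epcam-negative pair and 0.708 and 0.695 for replicate 2 with the fetal TEC pair. Day 10 replicates differed least (median chi-square 1.85 times its expectation for replicates 1 and 2) and the Epcam-positive pair most (1132 times).

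**Figure D1:**
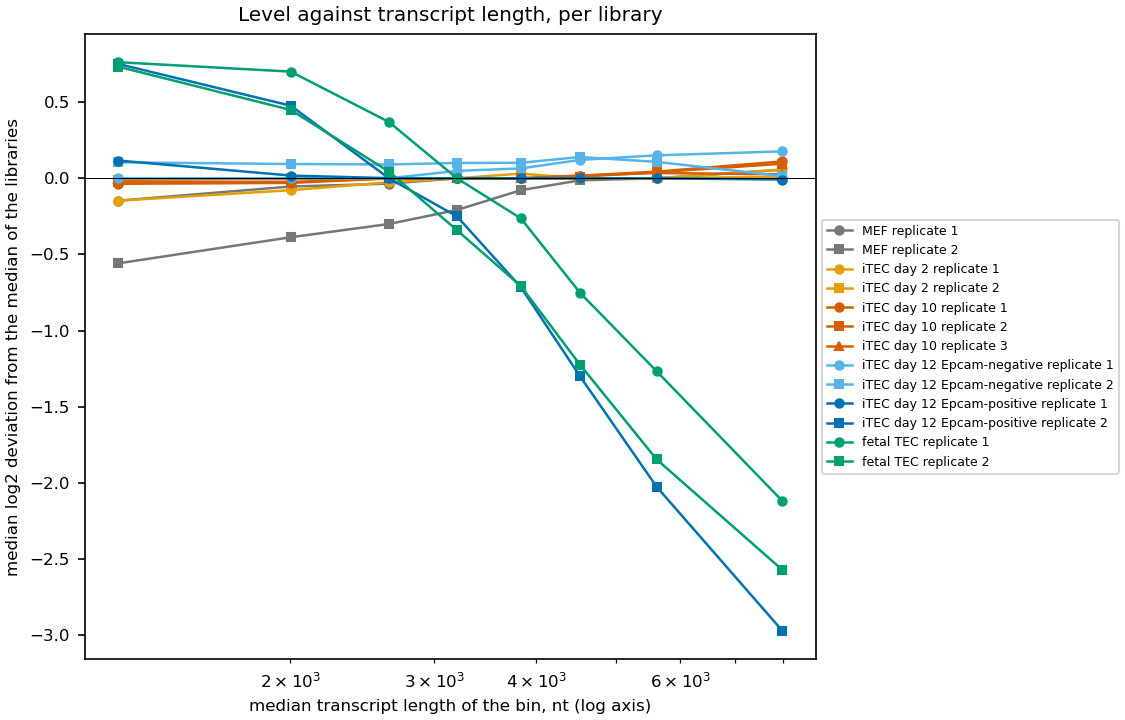
Median log2 deviation of each library from the median of all libraries (y) in 8 bins of genes by transcript length (x), for genes with a mean of at least 5 CPM. Epcam-positive replicate 2 (longest minus shortest bin -3.72) and both fetal TEC libraries (-2.88 and -3.31) slope down, and the other 10 libraries lie between -0.12 and 0.62.

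Sex-linked genes also split the groups, here in CPM by library size alone, as are list sums. Xist, the RNA of the inactive X chromosome, stood at 1266 and 2278 CPM in MEF and 1053 and 795 CPM in the Epcam-negative pair, with at most 0.02 CPM of the 4 Y-linked genes. Day 2, day 10 and Epcam-positive libraries held 46.3 to 326 CPM of Y-linked genes and at most 1.34 CPM of Xist, and fetal TEC held both (40.8 and 32.8 CPM of Y-linked genes, 6.05 and 8.21 CPM of Xist). MEF and Epcam-negative libraries thus differ in sex from the day 2, day 10 and Epcam-positive libraries, and comparisons across this line, the sort included, also compare embryos. Macrophage and dendritic cell genes summed to 3543 and 3424 CPM in MEF, 17.8 to 28.5 CPM in day 2, day 10 and Epcam-negative libraries, 285 and 64.8 CPM in the Epcam-positive pair, and 971 and 977 CPM in fetal TEC. Gapdh, a gene of glycolysis, was listed at 0 to 7.84 CPM in 10 libraries and at 99.2 to 147 CPM in the length-skewed ones. None of the 13 mitochondrially encoded genes of the list was in the table (0).

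**Figure D2:**
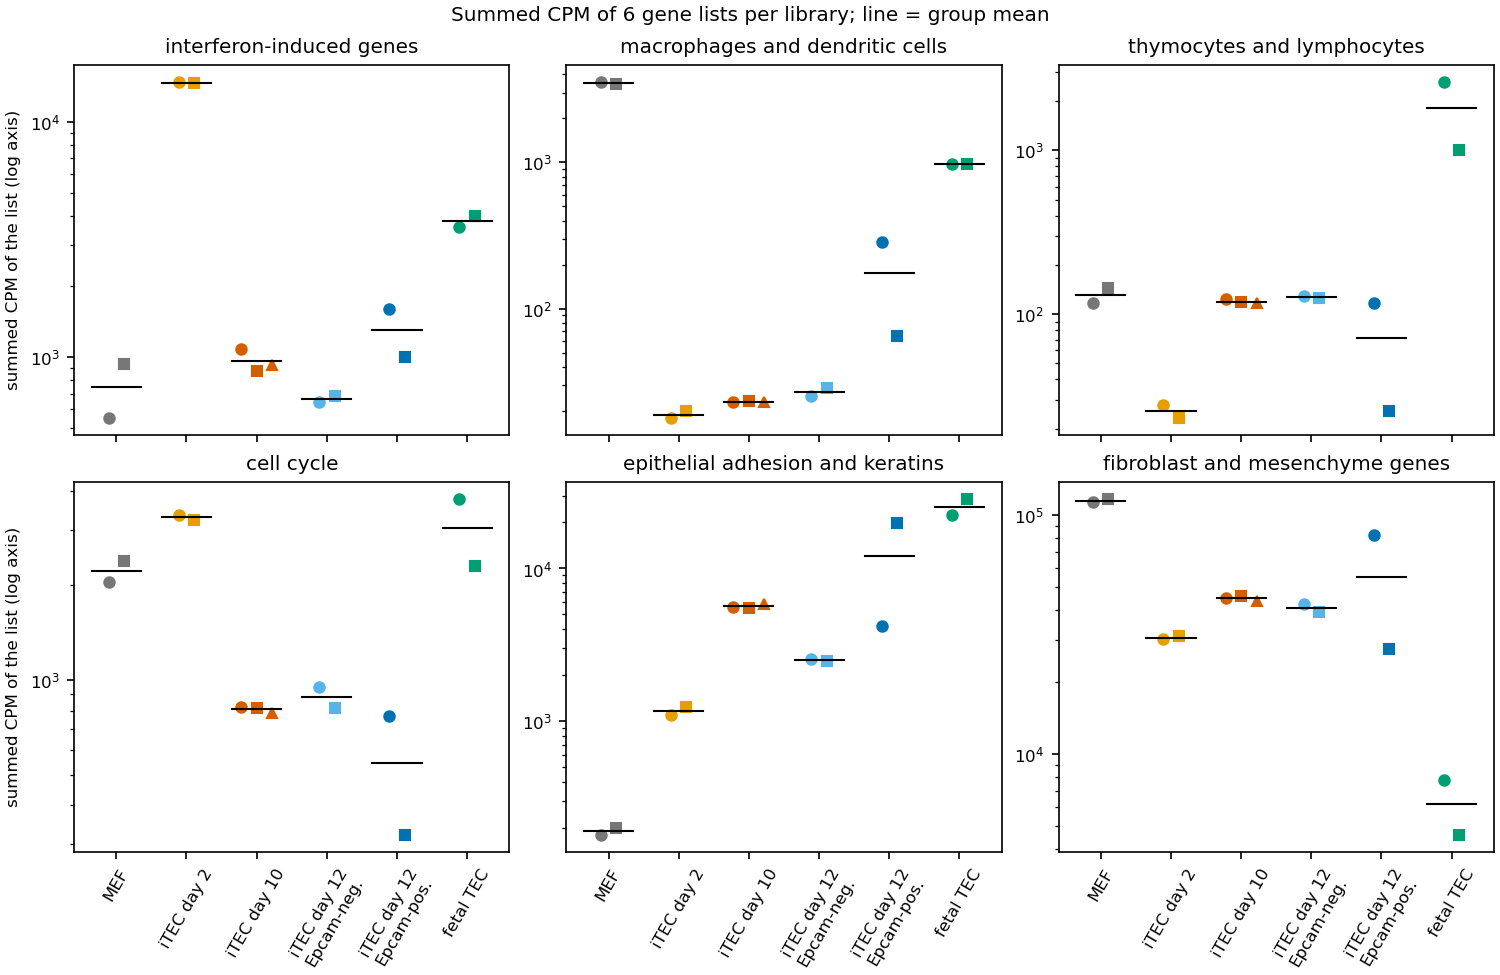
Summed CPM of gene lists (log scale) in each library, by group. Macrophage and dendritic cell genes reach 3543 CPM in MEF replicate 1 and 17.8 CPM in day 2 replicate 1, and interferon-induced genes 551 and 14787 CPM.

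Foxn1 was counted in MEF as well, and stood far above that level in every iTEC group and in fetal TEC. In the order MEF, day 2, day 10, Epcam-negative, Epcam-positive and fetal TEC, Foxn1 measured 15.7 ± 3.75, 341 ± 58.7, 431 ± 9.32, 429 ± 54.5, 309 ± 24.3 and 362 ± 0.599 CPM. Epcam, the surface protein used for sorting, measured 0, 0.117 ± 0.0369, 5.2 ± 0.285, 0.425 ± 0.191, 17.7 ± 18.3 and 443 ± 185 CPM. Dll4, the Notch ligand that directs progenitors to the T cell fate, measured 0, 27.7 ± 3.74, 101 ± 4.05, 147 ± 20.2, 139 ± 97.3 and 219 ± 25.6 CPM, and Ccl25, a chemokine that draws these progenitors in, 1.93 ± 0.142, 125 ± 10.1, 1619 ± 92.2, 1763 ± 53.8, 8103 ± 9690 and 3949 ± 1304 CPM. Psmb11, the proteasome subunit of cortical TEC, measured 0.027 ± 0.0186, 1.12 ± 0.145, 67.9 ± 2.44, 252 ± 17.8, 245 ± 217 and 2310 ± 741 CPM, and Prss16, their serine protease, 0.222 ± 0.116, 0.452 ± 0.28, 1.66 ± 0.265, 0.705 ± 0.0197, 12.8 ± 16.9 and 12870 ± 1856 CPM. Krt8, a keratin of simple epithelia and cortical TEC, measured 0.131 ± 0.127, 26.6 ± 3.68, 1467 ± 67.2, 585 ± 17.4, 6237 ± 6978 and 8382 ± 2815 CPM.

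**Figure D3:**
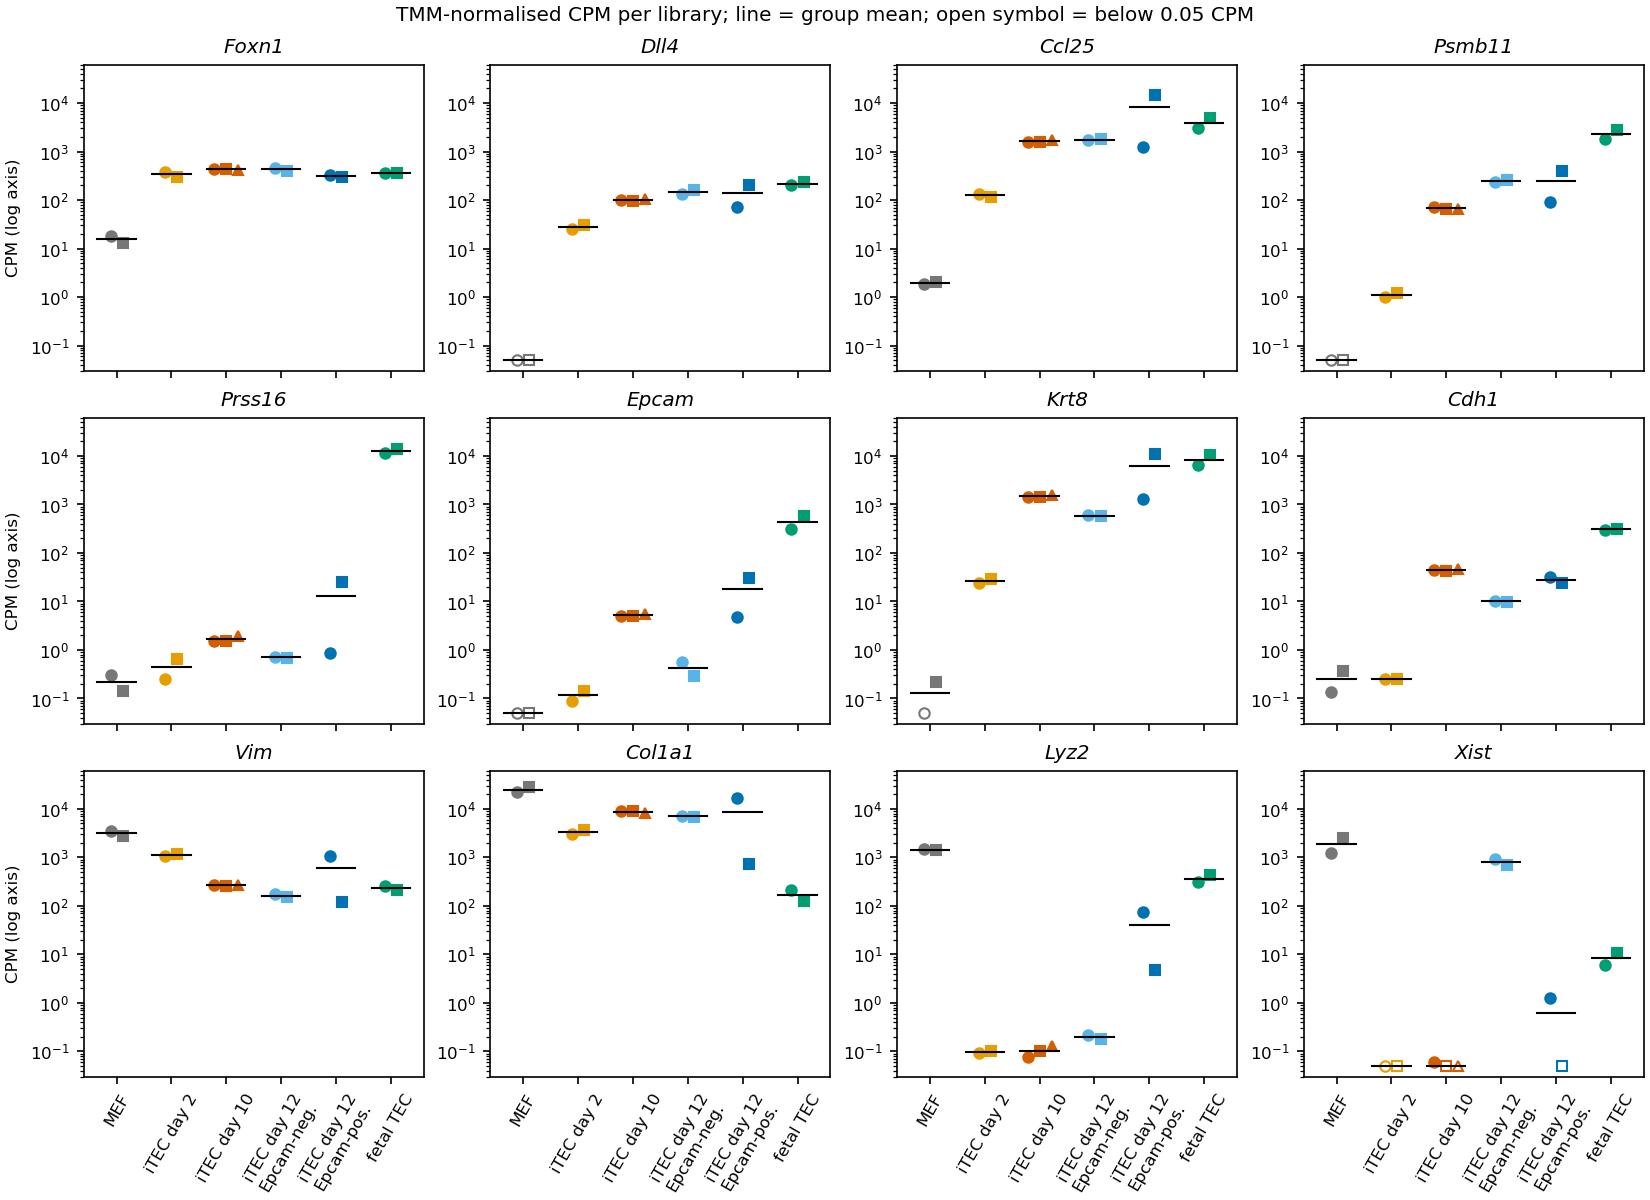
CPM (log scale) of the genes followed throughout, 1 point per library, by group. Foxn1 goes from 15.7 ± 3.75 CPM in MEF to 341 ± 58.7 CPM at day 2, and Prss16 reaches 12870 ± 1856 CPM in fetal TEC and 1.66 ± 0.265 CPM at day 10.

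The comparison of day 2 iTEC with MEF (n = 2 and 2) asks what changes first after Cre. Foxn1 rose (log2 4.44 ± 0.31, adjusted p = 0.000131). Dll4, with no count in MEF, rose as well (at least 1148-fold higher, adjusted p = 0.000146). Keratins of simple epithelia rose with it: Krt8 (log2 7.72 ± 1.14, adjusted p = 0.00418) and Krt18 (log2 10.46 ± 1.16, adjusted p = 0.000938). Ccl25 rose (log2 6.01 ± 0.99, adjusted p = 0.00734), and so did Psmb11 (ratio 46.2, counting interval 15.53 to 227, adjusted p = 0.00504). Kitl, the ligand of the Kit receptor of early progenitors, rose (log2 1.91 ± 0.37, adjusted p = 0.016), and the chemokine gene Cxcl12 fell (log2 -1.42 ± 0.34, adjusted p = 0.038). Epcam, Prss16, Krt5, Krt14, Cdh1, Vim, Col1a1 and Thy1 did not pass the test. Of 16 Foxn1-dependent TEC genes, 5 rose, 1 fell and 10 did not pass. Their median log2 change was 0.17 (adjusted p = 0.0573). Of 16 cortical TEC markers, 5 rose, 1 fell and 10 did not pass (6 and 1 over the list alone). The list moved by a median log2 of 0.9 (adjusted p = 0.000539, or 0.033 with an estimated correlation). Krt8 stood at a ratio of 651 (counting interval 223 to 3156) without MEF replicate 2. Ccl25 lost the call without MEF replicate 1 or 2 (adjusted p up to 0.0922). Psmb11 lost the call without MEF replicate 1 (adjusted p = 0.0685). Kitl lost the call without MEF replicate 1 or 2 or day 2 replicate 1 or 2 (adjusted p up to 0.108). Cxcl12 lost the call without any 1 library but Epcam-negative replicate 1 or 2 or Epcam-positive replicate 1 or 2 (adjusted p up to 0.294). The log2 change of Krt8 became 6.9 without MEF replicate 1. Epcam, Vim, Col1a1 and Thy1 passed without Epcam-positive replicate 1 or 2 (adjusted p up to 0.0217). Psmb11 stood at a ratio of 28.3 without MEF replicate 1 and 82.2 without replicate 2.

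The largest rises at day 2 included Y-linked genes, which split the groups together with Xist: Ddx3y (at least 3992-fold higher, adjusted p = 0.00017) and Uty (at least 1614-fold higher, adjusted p = 0.00114), then Eif2s3y (at least 1572-fold higher, adjusted p = 0.000414). Among the largest falls was Xist (at least 76760-fold lower, adjusted p = 0.00303).

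Antiviral genes rose broadly at day 2. Of 30 interferon-induced genes, 22 rose, 0 fell and 8 did not pass (30 and 0 over the list alone). As a list, the median log2 change was 4.43 (adjusted p = 1.47e-33, or 0.0309 with an estimated correlation). Irf7, the transcription factor that amplifies interferon production, rose from 8.2 ± 2.7 to 639.9 ± 4.97 CPM (log2 6.29 ± 0.4, adjusted p = 8.76e-05). Rsad2 rose as well (log2 7.32 ± 0.56, adjusted p = 0.000146). Of 16 MHC class I presentation genes, 9 rose, 0 fell and 7 did not pass (13 and 0 over the list alone). Camera gave adjusted p = 1.53e-13, or 0.00231 with an estimated correlation for the list, at a median log2 change of 2.82. Psmb8, of the immunoproteasome, rose (log2 3.64 ± 0.3, adjusted p = 0.000203). Of 22 inflammatory cytokines and chemokines, 3 rose, 0 fell and 19 did not pass (5 and 1 over the list alone). A median log2 change of 1.25 went with adjusted p = 0.00172, or 0.352 with an estimated correlation.

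Some fibroblast genes went down and some sterol genes up. Of 39 fibroblast and mesenchyme genes, 0 rose, 11 fell and 28 did not pass (0 and 16 over the list alone). Across members the median log2 change was -1.8 (adjusted p = 9.57e-13, or 0.167 with an estimated correlation). Dcn, the decorin gene, fell (log2 -5.04 ± 0.52, adjusted p = 0.000611). Of 22 cholesterol synthesis genes, 10 rose, 0 fell and 12 did not pass (16 and 0 over the list alone). For the list, camera gave adjusted p = 1.07e-13, or 0.0196 with an estimated correlation (median log2 change 1.25). Of 20 macrophage and dendritic cell genes, 1 rose, 9 fell and 10 did not pass (1 and 16 over the list alone). With a median log2 change of -10.29, the list had adjusted p = 1.53e-13, or 0.16 with an estimated correlation. Lyz2, the lysozyme of macrophages, went from 1452 ± 39.4 to 0.0973 ± 0.00936 CPM (log2 -13.83 ± 1.45, adjusted p = 0.000703). Fewer macrophages than in MEF and lower expression of their genes cannot be told apart from counts.

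In the day 2 test, edgeR called 938 genes, 488 higher and 450 lower (2979 at unadjusted p under 0.05). The groups did not overlap in 57.9% of tested genes, against 33.3% by chance. DESeq2 called 2205, and edgeR 6438 with only the 10 libraries without length skew. With 1 library left out, the count became 517 and 361 without MEF replicates 1 and 2, 301 and 299 without day 2 replicates 1 and 2, 573, 576 and 575 without day 10 replicates 1, 2 and 3, 597 and 594 without Epcam-negative replicates 1 and 2 and 3718 and 3716 without Epcam-positive replicates 1 and 2. Of the calls 52.0% were higher, but 49.6% with DESeq2 size factors or the length offset, 47.0% with DESeq2, 43.0% with only these groups and 46.9% without Epcam-positive replicate 1 or 2.

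Day 10 iTEC against MEF (n = 3 and 2) shows the later response, in which epithelial genes were abundant. Krt8 (log2 13.51 ± 1.37, adjusted p = 0.000251) and Krt18 (log2 11.02 ± 1.17, adjusted p = 0.00033) rose. Cdh1, the adhesion molecule E-cadherin, rose to 44.4 ± 2.12 CPM (log2 7.5 ± 0.47, adjusted p = 2.68e-05), and Epcam rose (at least 211-fold higher, adjusted p = 0.00129). Krt5 (at least 201-fold higher, adjusted p = 0.000754) and Krt14 (at least 149-fold higher, adjusted p = 0.0119) rose too. Vim, the intermediate filament of mesenchyme, fell (log2 -3.54 ± 0.67, adjusted p = 0.00695), and so did the surface protein gene Thy1 (log2 -3.74 ± 0.95, adjusted p = 0.0268). Col1a1 did not pass (log2 -1.5 ± 0.86, adjusted p = 0.289). Krt8 stood at a ratio of 35280 (counting interval 12070 to 171100) without MEF replicate 2. Krt14 lost the call without MEF replicate 1 or 2 (adjusted p up to 0.0813). Thy1 lost the call without MEF replicate 1 or 2 or day 10 replicate 1, 2 or 3 (adjusted p up to 0.149). Log2 changes moved to 12.66 (Krt8) and 6.91 (Cdh1) without MEF replicate 1 and to 8.3 (Cdh1) without replicate 2. Col1a1 passed without Epcam-positive replicate 1 or 2 (adjusted p up to 0.000831).

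Foxn1 stayed above MEF (log2 4.78 ± 0.31, adjusted p = 2.85e-05), and more genes of its list rose than fell. Among 16 Foxn1-dependent TEC genes, 7 rose, 3 fell and 6 did not pass (9 and 3 over the list alone). The list test gave adjusted p = 0.00114, or 0.028 with an estimated correlation, with a median log2 change of 2.72. Higher were Dll4 (at least 4097-fold higher, adjusted p = 3.93e-05) and Ccl25 (log2 9.71 ± 1.15, adjusted p = 0.000584), then Psmb11 (ratio 2788, counting interval 954 to 13520, adjusted p = 9.35e-05) and Kitl (log2 3.17 ± 0.38, adjusted p = 0.00056). Cxcl12 fell (log2 -3.34 ± 0.31, adjusted p = 0.000153), and Prss16 did not pass (log2 2.86 ± 1.12, adjusted p = 0.12). Among 16 cortical TEC markers, 8 rose, 1 fell and 7 did not pass (10 and 2 over the list alone). At their median, the log2 change was 2.72 (adjusted p = 0.000282, or 0.024 with an estimated correlation). 7 of 17 medullary TEC markers rose, 2 fell and 8 did not pass (adjusted p = 0.0368, or 0.367 with an estimated correlation). Medullary TEC markers as a list lost the call without MEF replicate 1 or 2, Epcam-positive replicate 1 or 2 or fetal TEC replicate 1 or 2 (adjusted p up to 0.103). Prss16 passed without Epcam-positive replicate 1 or 2 (adjusted p up to 0.000897). Psmb11 stood at a ratio of 1706 without MEF replicate 1 and 4951 without replicate 2.

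Hair keratin genes were among the largest rises, with Krt83 (at least 18830-fold higher, adjusted p = 0.000314) and Krt33a (at least 11090-fold higher, adjusted p = 0.00138). Others were Pkhd1l1 (at least 14330-fold higher, adjusted p = 0.00206) and the laminin gene Lamb3 (at least 12610-fold higher, adjusted p = 0.00066). Of 26 epidermal differentiation genes, 14 rose, 0 fell and 12 did not pass (17 and 0 over the list alone). On the log2 scale the list median was 4.82 (adjusted p = 2.27e-10, or 0.028 with an estimated correlation). Of 41 adhesion and keratin genes of epithelia, 30 rose, 2 fell and 9 did not pass (34 and 2 over the list alone). Log2 changes had a median of 6.68 (adjusted p = 6.56e-19, or 0.0163 with an estimated correlation).

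Fibroblast, growth and macrophage genes fell at day 10. Among 39 fibroblast and mesenchyme genes, 0 rose, 17 fell and 22 did not pass (2 and 27 over the list alone). In camera the list had adjusted p = 1.72e-09, or 0.18 with an estimated correlation (median log2 change -2.09). Of 40 cell cycle genes, 0 rose, 13 fell and 27 did not pass (0 and 20 over the list alone). Their median log2 change was -1.5 (adjusted p = 5.27e-11, or 0.159 with an estimated correlation). Among 20 macrophage and dendritic cell genes, 1 rose, 15 fell and 4 did not pass (1 and 17 over the list alone). The list moved by a median log2 of -8.97 (adjusted p = 1.33e-10, or 0.15 with an estimated correlation). Among the largest falls were the macrophage genes Stab1 (at least 12030-fold lower, adjusted p = 0.00875) and C1qa (at least 10950-fold lower, adjusted p = 0.0274), and Xist, the marker of the sex split (log2 -15.99 ± 1.77, adjusted p = 0.000648). Of 25 BMP and Wnt signalling genes, 12 rose, 2 fell and 11 did not pass (13 and 2 over the list alone). As a list, the median log2 change was 1.7 (adjusted p = 5.14e-05, or 0.0183 with an estimated correlation). C1qa lost the call without any 1 library but day 2 replicate 1 or 2, Epcam-negative replicate 1 or 2 or Epcam-positive replicate 1 or 2 (adjusted p up to 0.111). Xist stood at least 45150-fold lower without day 10 replicate 1.

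At day 10, edgeR called 2720 genes, 1601 higher and 1119 lower (5040 at unadjusted p under 0.05). No overlap was seen in 68.3% of tested genes (20% by chance). DESeq2 called 4222, and the 10 libraries without length skew gave 9231. Scaled by library size alone, 69.5% of calls were higher in place of 58.9%, and the median of all genes moved by 0.118 (log2). Leaving out 1 library gave 1568 and 1028 without MEF replicates 1 and 2, 1426, 1442 and 1410 without day 10 replicates 1, 2 and 3 and 6632 and 6650 without Epcam-positive replicates 1 and 2.

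Between day 2 and day 10 (n = 2 and 3) the antiviral response went back and epithelial genes went up. Among 30 interferon-induced genes, 0 rose, 30 fell and 0 did not pass. Camera gave adjusted p = 1.12e-28, or 0.0318 with an estimated correlation for the list, at a median log2 change of -4.11. Irf7 fell from 639.9 ± 4.97 to 14.8 ± 3.37 CPM (log2 -5.43 ± 0.32, adjusted p = 4.12e-05), and Rsad2 fell likewise (log2 -7.01 ± 0.46, adjusted p = 6.23e-05). Among 22 inflammatory cytokines and chemokines, 0 rose, 9 fell and 13 did not pass (0 and 11 over the list alone). A median log2 change of -2.59 went with adjusted p = 6.21e-09, or 0.0752 with an estimated correlation. Ccl5 fell (log2 -6.42 ± 0.76, adjusted p = 0.000732). Irg1, the itaconate enzyme of activated macrophages, fell (at least 487-fold lower, adjusted p = 0.00175). Among 40 cell cycle genes, 0 rose, 22 fell and 18 did not pass (0 and 30 over the list alone). Across members the median log2 change was -2.12 (adjusted p = 1.58e-21, or 0.0461 with an estimated correlation).

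Keratin and junction genes rose. Among 41 adhesion and keratin genes of epithelia, 29 rose, 1 fell and 11 did not pass (32 and 1 over the list alone). For the list, camera gave adjusted p = 6.95e-19, or 0.00672 with an estimated correlation (median log2 change 5.36). Cdh1 rose (log2 7.46 ± 0.47, adjusted p = 4.19e-05), and Epcam (log2 5.43 ± 0.9, adjusted p = 0.00522). Krt8 rose (log2 5.79 ± 0.98, adjusted p = 0.00468) and Krt18 did not pass (log2 0.56 ± 0.71, adjusted p = 0.734). Krt5 (at least 218-fold higher, adjusted p = 0.000889) and Krt14 (ratio 242, counting interval 66.6 to 2002, adjusted p = 0.0179) rose. Epcam, Krt8 and Krt14 lost the call without day 2 replicate 1 or 2 (adjusted p up to 0.078, 0.0782 and 0.169). Krt14 stood at a ratio of 141 without day 2 replicate 1 and at least 67.3-fold higher without replicate 2.

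Several TEC genes rose further while Foxn1 did not pass (log2 0.34 ± 0.25, adjusted p = 0.463). Of 16 Foxn1-dependent TEC genes, 6 rose, 1 fell and 9 did not pass (9 and 2 over the list alone). With a median log2 change of 1.68, the list had adjusted p = 0.0134, or 0.0574 with an estimated correlation. Of 16 cortical TEC markers, 8 rose, 2 fell and 6 did not pass (9 and 2 over the list alone). The list test gave adjusted p = 0.0294, or 0.0752 with an estimated correlation, with a median log2 change of 1.69. Psmb11 (log2 5.92 ± 0.68, adjusted p = 0.000641) and Dll4 (log2 1.86 ± 0.44, adjusted p = 0.0249) rose, and Ccl25 (log2 3.7 ± 0.86, adjusted p = 0.0203) and Kitl (log2 1.26 ± 0.34, adjusted p = 0.0378). Cxcl12 fell (log2 -1.92 ± 0.3, adjusted p = 0.00282), and Prss16 did not pass (log2 1.85 ± 1.04, adjusted p = 0.316). Of 15 Notch signalling genes, 7 rose, 0 fell and 8 did not pass (9 and 1 over the list alone). At their median, the log2 change was 1.68 (adjusted p = 9.32e-05, or 0.0461 with an estimated correlation). Heyl, a Notch target, rose (log2 7.88 ± 0.57, adjusted p = 9.01e-05). Dcn, which fell at day 2, rose again (log2 4.06 ± 0.48, adjusted p = 0.000714). Vim, Col1a1 and Thy1 did not pass. Cortical TEC markers as a list lost the call without fetal TEC replicate 1 or 2 (adjusted p up to 0.0911). Dll4 lost the call without any 1 library but MEF replicate 1 or 2, Epcam-positive replicate 1 or 2 or fetal TEC replicate 1 or 2 (adjusted p up to 0.222). Ccl25 lost the call without day 2 replicate 1 or 2 or day 10 replicate 1, 2 or 3 (adjusted p up to 0.177). Kitl lost the call without any 1 library but MEF replicate 1, Epcam-positive replicate 1 or 2 or fetal TEC replicate 1 (adjusted p up to 0.257). Prss16, Vim, Col1a1 and Thy1 passed without Epcam-positive replicate 1 or 2 (adjusted p up to 0.00601).

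From day 2 to day 10, edgeR called 2151 genes, 1401 higher and 750 lower (4303 at unadjusted p under 0.05). Groups were apart in 74.7% of genes, against 20% by chance. DESeq2 called 3606, and 8373 genes were called in the 10 libraries without length skew. The count was 564 and 623 without day 2 replicates 1 and 2, 1128, 1129 and 1127 without day 10 replicates 1, 2 and 3 and 5792 and 5782 without Epcam-positive replicates 1 and 2.

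The sort at day 12 asks what parts Epcam-positive from Epcam-negative cells (n = 2 and 2). Few genes passed. The positive pair differed widely, and the fractions also differ in sex and so in embryo. Krt19, a keratin of simple and basal epithelia, stood at 199.6 ± 209 against 6.37 ± 0.678 CPM (log2 4.97 ± 0.74, adjusted p = 0.0453). Epcam did not pass (17.7 ± 18.3 against 0.425 ± 0.191 CPM, log2 5.38 ± 0.88, adjusted p = 0.0632), with replicate 1 below day 10. Krt5 was at 21.8 ± 0.215 against 1.09 ± 0.977 CPM (log2 4.33 ± 0.67, adjusted p = 0.0649). Foxn1, Dll4, Ccl25, Psmb11, Prss16, Kitl, Cxcl12, Krt8, Krt14, Krt18, Cdh1, Vim, Col1a1 and Thy1 did not pass either. Krt19 lost the call without any 1 library but Epcam-positive replicate 1 or 2 (adjusted p up to 0.561). The log2 change of Krt19 became 5.76 without Epcam-positive replicate 1 and 3.03 without replicate 2. With Epcam-positive replicate 2 as the only library of its group, log2 changes were 6.19 (Epcam), 3.08 (Ccl25), 5.13 (Prss16) and -2.27 (Kitl). Others were 4.25 (Krt8), 3.93 (Krt18), -3.28 (Col1a1) and -2.1 (Thy1). With replicate 1 as the only one, they were 3.52 (Epcam), -1.06 (Dll4), -1.46 (Psmb11), 2.75 (Vim) and 2.72 (Thy1), so Thy1 changed sign. Neither fit measures the spread of Epcam-positive cells.

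Y-linked genes were among the largest differences: Eif2s3y (at least 1850-fold higher, adjusted p = 0.0111) and Ddx3y (ratio 17260, counting interval 3097 to 681800, adjusted p = 0.00393), then Uty (at least 1043-fold higher, adjusted p = 0.0215). Lyz2 was higher (log2 7.67 ± 1.15, adjusted p = 0.0453), at 76.1 CPM in Epcam-positive replicate 1 and 4.72 CPM in replicate 2. Of 20 macrophage and dendritic cell genes, 1 was higher, 0 lower and 19 did not pass (12 and 0 over the list alone). On the log2 scale the list median was 5.82 (adjusted p = 9.83e-06, or 0.558 with an estimated correlation). Lower were Ildr2 (log2 -2.97 ± 0.48, adjusted p = 0.0493) and Rgs17 (log2 -2.29 ± 0.29, adjusted p = 0.0216), and Apcdd1, an inhibitor of Wnt signalling (log2 -2.0 ± 0.26, adjusted p = 0.0224). With the length trend as an offset, the log2 change of Apcdd1 was 0.005. Eif2s3y lost the call without day 10 replicate 1, 2 or 3 or Epcam-negative replicate 1 or 2 (adjusted p up to 0.145). Ddx3y lost the call without Epcam-negative replicate 1 or 2 (adjusted p up to 0.0964). Uty lost the call without any 1 library but MEF replicate 1 or 2 or Epcam-positive replicate 1 or 2 (adjusted p up to 0.274). Lyz2 and Ildr2 lost the call without any 1 library but Epcam-positive replicate 1 or 2 (adjusted p up to 0.576 and 0.548). Macrophage and dendritic cell genes as a list lost the call without Epcam-positive replicate 1 (adjusted p = 0.366). Rgs17 and Apcdd1 lost the call without any 1 library but MEF replicate 2, Epcam-positive replicate 1 or 2 or fetal TEC replicate 1 or 2 (adjusted p up to 0.274 and 0.347). Log2 changes moved to 4.57 (Lyz2) and -3.92 (Ildr2) without Epcam-positive replicate 1 and to 8.59 (Lyz2) without replicate 2. Eif2s3y stood at least 683-fold higher without Epcam-positive replicate 1. Ddx3y stood at least 3391-fold higher without Epcam-negative replicate 1, at a ratio of 7086 without replicate 2 and 7343 without Epcam-positive replicate 1. Uty stood at least 264-fold higher without Epcam-positive replicate 1.

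Adhesion, keratin and epidermal genes moved upward as lists while few members passed, and so did medullary TEC markers. Of 41 adhesion and keratin genes of epithelia, 1 was higher, 0 lower and 40 did not pass (28 and 0 over the list alone). Log2 changes had a median of 2.75 (adjusted p = 8.81e-14, or 0.0371 with an estimated correlation). Among 26 epidermal differentiation genes, 2 were higher, 0 lower and 24 did not pass (12 and 0 over the list alone). In camera the list had adjusted p = 5.70e-08, or 0.0768 with an estimated correlation (median log2 change 3.27). 0 of 17 medullary TEC markers were higher, 0 lower and 17 did not pass (6 and 1 over the list alone, adjusted p = 0.00503, or 0.476 with an estimated correlation). 0 of 20 epithelial transcription and splicing regulators were higher, 0 lower and 20 did not pass (4 and 0 over the list alone, adjusted p = 0.455). 1 of 17 simple epithelium and mesothelium genes were higher, 0 lower and 16 did not pass (5 and 1 over the list alone, adjusted p = 0.591). Of 30 interferon-induced genes, 3 were higher, 0 lower and 27 did not pass (12 and 0 over the list alone). Their median log2 change was 1.24 (adjusted p = 7.96e-06, or 0.558 with an estimated correlation). Among 16 Foxn1-dependent TEC genes, 0 were higher, 0 lower and 16 did not pass (2 and 2 over the list alone). Foxn1-dependent TEC genes had a median log2 change of 0.02 (mean 0.24, test downward, adjusted p = 0.73). Epidermal differentiation genes as a list, medullary TEC markers as a list and interferon-induced genes as a list lost the call without Epcam-positive replicate 1 (adjusted p = 0.0541, 0.401 and 0.574).

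Between the sorted fractions, edgeR called 44 genes, 41 higher and 3 lower (3261 at unadjusted p under 0.05). DESeq2 called 1737. Groups were apart in 45.4% of genes (33.3% by chance). The 10 libraries without length skew gave 1651, where Epcam-positive replicate 1 stood alone and was assumed to vary like the other groups. With library size alone, 7 genes were called, 71.4% of them higher in place of 93.2%, and the median of all genes moved by -0.242 (log2). Each left-out library moved the count: 5 and 16 without MEF replicates 1 and 2, 3 and 3 without day 2 replicates 1 and 2, 1, 1 and 1 without day 10 replicates 1, 2 and 3, 0 and 0 without Epcam-negative replicates 1 and 2, 9545 and 500 without Epcam-positive replicates 1 and 2 and 11 and 15 without fetal TEC replicates 1 and 2. Without Epcam-positive replicate 1 the balance turned (43.1% higher), in a fit with 1 length-skewed library as the positive group. Where the count was 0, 979 and 1178 genes stood at unadjusted p under 0.05.

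Epcam-positive cells against MEF (n = 2 and 2) show how far the sorted cells had moved from fibroblasts. Among the large rises was the skin gene Calm4 (at least 26620-fold higher, adjusted p = 0.0014). Epcam rose (at least 521-fold higher, adjusted p = 0.000893). Krt8 (log2 15.59 ± 1.46, adjusted p = 0.000236) and Krt18 (log2 13.43 ± 1.28, adjusted p = 0.000259) rose, and Krt5 (at least 885-fold higher, adjusted p = 0.000514) and Krt14 (at least 512-fold higher, adjusted p = 0.0081). Cdh1 rose (log2 6.83 ± 0.47, adjusted p = 5.77e-05). Foxn1 rose (log2 4.3 ± 0.31, adjusted p = 5.94e-05), as did Dll4 (at least 4607-fold higher, adjusted p = 5.77e-05) and Psmb11 (ratio 7603, counting interval 2601 to 36870, adjusted p = 6.97e-05), and Ccl25 (log2 12.04 ± 1.26, adjusted p = 0.000402) and Prss16 (log2 5.8 ± 1.3, adjusted p = 0.0163). Kitl rose (log2 1.65 ± 0.37, adjusted p = 0.016), and Cxcl12 fell (log2 -3.07 ± 0.36, adjusted p = 0.000634). Vim, Col1a1 and Thy1 did not pass. Among 41 adhesion and keratin genes of epithelia, 32 rose, 1 fell and 8 did not pass (33 and 2 over the list alone). The list moved by a median log2 of 6.47 (adjusted p = 7.10e-14, or 0.0417 with an estimated correlation). Of 16 Foxn1-dependent TEC genes, 9 rose, 2 fell and 5 did not pass (10 and 2 over the list alone). As a list, the median log2 change was 2.98 (adjusted p = 0.00758, or 0.0584 with an estimated correlation). Krt8 stood at a ratio of 105100 (counting interval 35950 to 509400) without MEF replicate 2. Krt14 lost the call without MEF replicate 2 (adjusted p = 0.072). Prss16 and Kitl lost the call without MEF replicate 1 or 2 (adjusted p up to 0.16 and 0.0829). Log2 changes went to 14.77 (Krt8), 6.23 (Cdh1) and 6.48 (Prss16) without MEF replicate 1, to 7.64 (Cdh1) without replicate 2, to 16.50 (Krt8), 14.29 (Krt18), 12.92 (Ccl25), 6.72 (Prss16) and 0.94 (Kitl) without Epcam-positive replicate 1 and to 13.40 (Krt8), 10.93 (Krt18), 9.35 (Ccl25) and 1.91 (Prss16) without replicate 2. With Epcam-positive replicate 2 as the only library of its group, log2 changes were -4.69 (Vim), -5.09 (Col1a1) and -7.28 (Thy1). With replicate 1 as the only one, they were -1.51 (Vim) and -2.46 (Thy1). Calm4 stood at least 78060-fold higher without Epcam-positive replicate 1 and 3572-fold without replicate 2. Epcam stood at least 1248-fold higher without Epcam-positive replicate 1 and 195-fold without replicate 2. Dll4 stood at least 8479-fold higher without Epcam-positive replicate 1 and 2872-fold without replicate 2. Psmb11 stood at a ratio of 4653 without MEF replicate 1, 13500 without replicate 2, 16220 without Epcam-positive replicate 1 and 3744 without replicate 2.

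Cd74, the invariant chain of MHC class II, rose to 161 ± 138 CPM in the positive cells (log2 10.45 ± 0.94, adjusted p = 0.000197), with 40.1 and 53.3 CPM in the Epcam-negative pair. 3 of 12 MHC class II presentation genes rose, 0 fell and 9 did not pass (median log2 change -0.19, mean 1.64, test upward, adjusted p = 0.811). Of 40 cell cycle genes, 0 rose, 15 fell and 25 did not pass (0 and 21 over the list alone). Camera gave adjusted p = 3.81e-11, or 0.145 with an estimated correlation for the list, at a median log2 change of -2.05. Here edgeR called 3455 genes, 2707 higher and 748 lower (6525 at unadjusted p under 0.05). Of these, 3421 had no overlap, as did 55.4% of tested genes (33.3% by chance). DESeq2 called 6171, and the 10 libraries without length skew 6572. Left-out libraries gave 1822 and 669 without MEF replicates 1 and 2, 2228 and 2229 without day 2 replicates 1 and 2, 2122, 2121 and 2134 without day 10 replicates 1, 2 and 3, 2074 and 2076 without Epcam-negative replicates 1 and 2 and 10819 without Epcam-positive replicate 1. The excess of higher genes turned without that library (45.7% higher in place of 78.4%), which left 1 length-skewed library in the group. With the 10 libraries 56.8% were higher. The log2 change of Cd74 became 11.12 without Epcam-positive replicate 1 and 9.09 without replicate 2.

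Epcam-negative cells against MEF (n = 2 and 2) ask whether programming reached cells outside the sort gate. TEC genes were up in them as well: Dll4 (at least 6098-fold higher, adjusted p = 5.19e-05) and Psmb11 (ratio 10350, counting interval 3543 to 50210, adjusted p = 6.20e-05). Foxn1 rose (log2 4.78 ± 0.32, adjusted p = 4.39e-05), and Ccl25 (log2 9.84 ± 1.17, adjusted p = 0.000715) and Kitl (log2 3.21 ± 0.39, adjusted p = 0.000796). Cxcl12 fell (log2 -4.25 ± 0.38, adjusted p = 0.000158), and Prss16 did not pass (log2 1.63 ± 1.14, adjusted p = 0.429). Among keratins, Krt8 (log2 12.18 ± 1.32, adjusted p = 0.000462) and Krt18 (log2 10.36 ± 1.16, adjusted p = 0.000526) rose, and Krt5 (at least 39.4-fold higher, adjusted p = 0.00316). Cdh1 rose (log2 5.36 ± 0.44, adjusted p = 0.0001), and Epcam (at least 16.3-fold higher, adjusted p = 0.0168). Pkhd1l1 was among the largest rises (at least 18410-fold higher, adjusted p = 0.00236). Vim fell (log2 -4.26 ± 0.81, adjusted p = 0.00947) and Thy1 fell (log2 -5.19 ± 1.2, adjusted p = 0.0225), whereas Col1a1 and Krt14 did not pass. Among 16 Foxn1-dependent TEC genes, 7 rose, 1 fell and 8 did not pass (8 and 2 over the list alone). A median log2 change of 2.42 went with adjusted p = 0.0003, or 0.0314 with an estimated correlation. Of 41 adhesion and keratin genes of epithelia, 24 rose, 1 fell and 16 did not pass (29 and 3 over the list alone). Across members the median log2 change was 3.63 (adjusted p = 1.32e-09, or 0.0457 with an estimated correlation). Krt8 stood at a ratio of 14060 (counting interval 4810 to 68160) without MEF replicate 2. Epcam lost the call without MEF replicate 1 or 2 or Epcam-negative replicate 1 (adjusted p up to 0.091). Vim lost the call without Epcam-negative replicate 1 or 2 (adjusted p up to 0.101). Thy1 lost the call without MEF replicate 2 or Epcam-negative replicate 1 or 2 (adjusted p up to 0.176). Log2 changes moved to 11.34 (Krt8) without MEF replicate 1, to 6.17 (Cdh1) without replicate 2 and to -4.86 (Cxcl12) without Epcam-negative replicate 2. Prss16 and Col1a1 passed without Epcam-positive replicate 1 or 2 (adjusted p up to 0.0237). Krt14 stood at 0.546 CPM in Epcam-negative replicate 1 and at 0 in replicate 2. Psmb11 stood at a ratio of 6336 without MEF replicate 1 and 18390 without replicate 2. Krt5 stood at least 16.3-fold higher without Epcam-negative replicate 1 and 72.6-fold without replicate 2.

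Macrophage genes were below MEF in the negative cells too. Among 20 macrophage and dendritic cell genes, 1 rose, 11 fell and 8 did not pass (1 and 17 over the list alone). For the list, camera gave adjusted p = 6.13e-10, or 0.151 with an estimated correlation (median log2 change -9.52). Against MEF, edgeR called 2025 genes, 1254 higher and 771 lower (4429 at unadjusted p under 0.05). In 69.8% of genes the groups were apart (33.3% by chance). DESeq2 called 3642, and the 10 libraries without length skew 8671. By library size alone 75.7% of calls were higher in place of 61.9%, with a shift of the median of all genes of 0.227 (log2). Single left-out libraries gave 1147 and 741 without MEF replicates 1 and 2, 1322 and 1348 without day 10 replicates 1 and 2, 719 and 727 without Epcam-negative replicates 1 and 2 and 5897 and 5885 without Epcam-positive replicates 1 and 2.

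Fetal TEC against MEF (n = 2 and 2) set the distance that programming would have to cover. MHC class II and TEC genes were among the largest differences. H2-Aa, a chain of MHC class II, stood at 9170 ± 3699 CPM (at least 358700-fold higher, adjusted p = 0.00123). Tbata, a gene of thymic epithelium, was also higher (at least 146100-fold higher, adjusted p = 0.000229), as was the keratin gene Krt17 (at least 147500-fold higher, adjusted p = 0.000259). Prss16 (log2 15.78 ± 1.82, adjusted p = 0.000252) and Psmb11 (ratio 91120, counting interval 31180 to 441800, adjusted p = 1.98e-05) were higher, and Dll4 (at least 8801-fold higher, adjusted p = 1.98e-05) and Ccl25 (log2 11.001 ± 1.22, adjusted p = 0.000202). Foxn1 was higher (log2 4.53 ± 0.31, adjusted p = 2.21e-05), and Cxcl12 (log2 1.88 ± 0.34, adjusted p = 0.00217). Kitl did not pass (log2 -0.55 ± 0.36, adjusted p = 0.208), and with the length trend as an offset it passed in the other direction (log2 0.99, adjusted p = 0.00632). The log2 change of Prss16 became 16.47 without MEF replicate 1. Kitl passed without Epcam-positive replicate 1 or 2 (adjusted p up to 0.0117). Psmb11 stood at a ratio of 55760 without MEF replicate 1 and 161800 without replicate 2.

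Epithelial and mesenchymal genes parted fetal TEC from MEF. Higher were Epcam (at least 17310-fold higher, adjusted p = 0.000114) and Cdh1 (log2 10.29 ± 0.53, adjusted p = 1.59e-05). Krt8 (log2 16.02 ± 1.48, adjusted p = 8.89e-05) and Krt18 (log2 14.11 ± 1.31, adjusted p = 9.11e-05) were higher, as were Krt5 (at least 14530-fold higher, adjusted p = 8.61e-05) and Krt14 (at least 11330-fold higher, adjusted p = 0.000823). Lower were Vim (log2 -3.74 ± 0.79, adjusted p = 0.00454) and Col1a1 (log2 -7.21 ± 1.25, adjusted p = 0.00183), and Thy1 (log2 -6.86 ± 1.3, adjusted p = 0.00277). Among 41 adhesion and keratin genes of epithelia, 39 were higher, 0 lower and 2 did not pass (40 and 0 over the list alone). With a median log2 change of 10.16, the list had adjusted p = 4.49e-16, or 0.0185 with an estimated correlation. Of 39 fibroblast and mesenchyme genes, 1 was higher, 32 lower and 6 did not pass. The list test gave adjusted p = 1.23e-10, or 0.126 with an estimated correlation, with a median log2 change of -4.86. Of 11 transcription factors of the epithelial-mesenchymal transition, 0 were higher, 9 lower and 2 did not pass. At their median, the log2 change was -4.52 (adjusted p = 0.000404, or 0.152 with an estimated correlation). Of 22 TGF-beta response and myofibroblast genes, 0 were higher, 21 lower and 1 did not pass. On the log2 scale the list median was -3.9 (adjusted p = 9.85e-09, or 0.121 with an estimated correlation). Krt8 stood at a ratio of 195400 (counting interval 66880 to 947800) without MEF replicate 2. Log2 changes went to 15.21 (Krt8) without MEF replicate 1 and to 11.08 (Cdh1) without replicate 2.

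TEC lists were higher almost throughout. Of 16 Foxn1-dependent TEC genes, 15 were higher, 0 lower and 1 did not pass. Log2 changes had a median of 7.36 (adjusted p = 2.85e-07, or 0.0183 with an estimated correlation). Among 16 cortical TEC markers, 14 were higher, 1 lower and 1 did not pass. In camera the list had adjusted p = 5.29e-06, or 0.0185 with an estimated correlation (median log2 change 6.82). Of 17 medullary TEC markers, 14 were higher, 0 lower and 3 did not pass. Their median log2 change was 11.30 (adjusted p = 5.19e-07, or 0.0655 with an estimated correlation). Of 16 factors of pouch and thymus fate, 10 were higher, 3 lower and 3 did not pass. The list moved by a median log2 of 2.98 (adjusted p = 0.0345, or 0.302 with an estimated correlation). Of 12 MHC class II presentation genes, 7 were higher, 1 lower and 4 did not pass. As a list, the median log2 change was 3.12 (adjusted p = 0.0142, or 0.312 with an estimated correlation). Cd74 was higher (log2 18.02 ± 1.17, adjusted p = 1.98e-05). Among 16 MHC class I presentation genes, 11 were higher, 2 lower and 3 did not pass. Camera gave adjusted p = 0.000798, or 0.0321 with an estimated correlation for the list, at a median log2 change of 3.64. Factors of pouch and thymus fate as a list lost the call without MEF replicate 1 or fetal TEC replicate 1 or 2 (adjusted p up to 0.0822). MHC class II presentation genes as a list lost the call without fetal TEC replicate 2 (adjusted p = 0.0708). The log2 change of Cd74 became 17.36 without fetal TEC replicate 2.

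Genes of other cell types were counted in the fetal TEC libraries. Of 25 thymocyte and lymphocyte genes, 21 were higher, 0 lower and 4 did not pass. A median log2 change of 8.59 went with adjusted p = 1.42e-08, or 0.152 with an estimated correlation. 18 of 24 skeletal muscle genes were higher, 1 lower and 5 did not pass (19 and 2 over the list alone, adjusted p = 3.10e-05, or 0.114 with an estimated correlation). 8 of 11 erythroid genes were higher, 0 lower and 3 did not pass (9 and 0 over the list alone, adjusted p = 0.000975, or 0.0339 with an estimated correlation). 12 of 16 endothelial genes were higher, 0 lower and 4 did not pass (adjusted p = 0.00109, or 0.133 with an estimated correlation). 5 of 7 parathyroid genes were higher, 1 lower and 1 did not pass (adjusted p = 0.0237, or 0.109 with an estimated correlation). 3 of 20 macrophage and dendritic cell genes were higher, 6 lower and 11 did not pass (1 and 4 over the list alone, adjusted p = 0.0486, or 0.57 with an estimated correlation). 8 of 16 neural and neural crest genes were higher, 4 lower and 4 did not pass (adjusted p = 0.292). 6 of 18 cartilage and bone genes were higher, 4 lower and 8 did not pass (median log2 change -0.08, mean 0.33, test downward, adjusted p = 0.708). 3 of 10 adipocyte genes were higher, 1 lower and 6 did not pass (median log2 change -0.41, mean 2.31, test upward, adjusted p = 0.907). Parathyroid genes as a list lost the call without Epcam-positive replicate 1 or 2 (adjusted p up to 0.0697). Macrophage and dendritic cell genes as a list lost the call without MEF replicate 1 or 2 or fetal TEC replicate 1 or 2 (adjusted p up to 0.122).

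Further epithelial lists and signalling lists gave these counts. 15 of 20 epithelial transcription and splicing regulators were higher, 1 lower and 4 did not pass (15 and 2 over the list alone, adjusted p = 7.07e-05, or 0.0321 with an estimated correlation). 15 of 17 simple epithelium and mesothelium genes were higher, 0 lower and 2 did not pass (adjusted p = 4.17e-05, or 0.0198 with an estimated correlation). 20 of 26 epidermal differentiation genes were higher, 0 lower and 6 did not pass (adjusted p = 1.97e-06, or 0.0779 with an estimated correlation). 15 of 22 cholesterol synthesis genes were higher, 0 lower and 7 did not pass (adjusted p = 0.000112, or 0.0844 with an estimated correlation). 18 of 30 interferon-induced genes were higher, 1 lower and 11 did not pass (adjusted p = 0.00109, or 0.371 with an estimated correlation). 16 of 40 cell cycle genes were higher, 3 lower and 21 did not pass (15 and 3 over the list alone, adjusted p = 0.0346, or 0.57 with an estimated correlation). 5 of 24 p53 target and senescence genes were higher, 11 lower and 8 did not pass (adjusted p = 0.0936). 7 of 22 inflammatory cytokines and chemokines were higher, 6 lower and 9 did not pass (adjusted p = 0.907). 8 of 15 Notch signalling genes were higher, 4 lower and 3 did not pass (adjusted p = 0.129). 9 of 25 BMP and Wnt signalling genes were higher, 9 lower and 7 did not pass (median log2 change 0.2, mean 0.27, test downward, adjusted p = 0.984). By fry, which asks whether genes move 1 way on balance, the BMP and Wnt list had adjusted p = 0.0304 upward. Cell cycle genes as a list lost the call without MEF replicate 1, Epcam-positive replicate 1 or 2 or fetal TEC replicate 1 (adjusted p up to 0.0663).

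Between the controls, edgeR called 9831 genes, 5363 higher and 4468 lower (10757 at unadjusted p under 0.05), 9779 of them without overlap. Across tested genes 79.9% had no overlap (33.3% by chance). Both fetal TEC libraries are length-skewed and MEF are not. The median log2 change of all genes was 0.184. It moved by 0.138 with DESeq2 size factors, by -0.143 with library size alone and by 0.114 with the length offset. The count was 5507 without MEF replicate 2. There, more genes were lower than higher (47.4% higher in place of 54.6%).

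Epcam-positive cells against fetal TEC (n = 2 and 2) show what still parts the programmed cells from the thymus. Foxn1 did not pass (log2 -0.23 ± 0.27, adjusted p = 0.533), nor did Dll4, Ccl25, Krt8, Krt18 and Vim. Prss16 was far lower, 12.8 ± 16.9 against 12870 ± 1856 CPM (log2 -9.98 ± 1.5, adjusted p = 0.00146). Lower were also Psmb11 (log2 -3.24 ± 0.61, adjusted p = 0.00419) and Cxcl12 (log2 -4.94 ± 0.39, adjusted p = 6.18e-05), and Epcam (log2 -4.65 ± 0.83, adjusted p = 0.00429) and Cdh1 (log2 -3.45 ± 0.39, adjusted p = 0.000331). Basal keratins were lower: Krt5 (log2 -4.06 ± 0.66, adjusted p = 0.00366) and Krt14 (log2 -4.65 ± 1.27, adjusted p = 0.023). Kitl was higher (log2 2.2 ± 0.37, adjusted p = 0.00249). Col1a1 was higher (log2 5.69 ± 1.17, adjusted p = 0.00613), and Thy1, whose samples overlap, too (log2 3.45 ± 1.11, adjusted p = 0.0367). Krt14 and Col1a1 lost the call without fetal TEC replicate 2 (adjusted p = 0.0774 and 0.0522). Thy1 lost the call without any 1 library but Epcam-positive replicate 2 (adjusted p up to 0.494). Log2 changes moved to -9.01 (Prss16), -2.52 (Psmb11), -3.84 (Epcam), 1.5 (Kitl), 2.13 (Col1a1) and -0.4 (Thy1) without Epcam-positive replicate 1 and to -13.83 (Prss16), -4.64 (Psmb11), -6.51 (Epcam), 6.64 (Col1a1) and 4.42 (Thy1) without replicate 2. With Epcam-positive replicate 1 as the only library of its group, log2 changes were -1.62 (Dll4), -1.64 (Ccl25), -2.67 (Krt8), -3.17 (Krt18) and 2.24 (Vim). With replicate 2 as the only one, they were 1.93 (Ccl25) and -0.94 (Vim).

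TEC lists remained below the fetal level. Among 16 Foxn1-dependent TEC genes, 1 was higher, 10 lower and 5 did not pass. Across members the median log2 change was -2.82 (adjusted p = 2.49e-05, or 0.0554 with an estimated correlation). Of 16 cortical TEC markers, 1 was higher, 9 lower and 6 did not pass. For the list, camera gave adjusted p = 0.00089, or 0.0654 with an estimated correlation (median log2 change -2.09). Among 17 medullary TEC markers, 0 were higher, 12 lower and 5 did not pass (1 and 12 over the list alone). With a median log2 change of -4.65, the list had adjusted p = 1.70e-06, or 0.072 with an estimated correlation. Fezf2, a regulator of self-antigen genes in the medulla, had no count in the sorted cells (at least 6816-fold lower, adjusted p = 0.00122). Pax1 and Trp63, of pouch and progenitor fate, were lower: Pax1 (log2 -10.73 ± 1.19, adjusted p = 0.000328) and Trp63 (log2 -8.44 ± 1.35, adjusted p = 0.00195). Among 12 MHC class II presentation genes, 1 was higher, 6 lower and 5 did not pass. The list test gave adjusted p = 0.000114, or 0.135 with an estimated correlation, with a median log2 change of -3.72. Cd74 was lower (log2 -7.58 ± 0.82, adjusted p = 0.000285). Pax1 stood at least 5688-fold lower without Epcam-positive replicate 1. Trp63 stood at least 2326-fold lower without Epcam-positive replicate 1. Log2 changes moved to -6.88 (Cd74) without Epcam-positive replicate 1, to -9.86 (Pax1), -7.51 (Trp63) and -8.91 (Cd74) without replicate 2 and to -6.91 (Cd74) without fetal TEC replicate 2.

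Junction and growth genes were lower and mesenchymal genes higher than in fetal TEC. Of 41 adhesion and keratin genes of epithelia, 1 was higher, 17 lower and 23 did not pass (1 and 19 over the list alone). At their median, the log2 change was -2.41 (adjusted p = 5.32e-06, or 0.0901 with an estimated correlation). Among 39 fibroblast and mesenchyme genes, 26 were higher, 2 lower and 11 did not pass (29 and 3 over the list alone). On the log2 scale the list median was 3.38 (adjusted p = 3.37e-06, or 0.26 with an estimated correlation). Among 40 cell cycle genes, 0 were higher, 27 lower and 13 did not pass (0 and 29 over the list alone). Log2 changes had a median of -2.71 (adjusted p = 4.90e-13, or 0.094 with an estimated correlation). Among 25 thymocyte and lymphocyte genes, 0 were higher, 21 lower and 4 did not pass. In camera the list had adjusted p = 3.29e-13, or 0.0849 with an estimated correlation (median log2 change -8.63).

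Cemip was among the genes above fetal TEC (at least 18910-fold higher, adjusted p = 0.00105). The airway gene Bpifa1 was lower (at least 48810-fold lower, adjusted p = 0.000921). For these groups edgeR called 6052 genes, 3263 higher and 2789 lower (8030 at unadjusted p under 0.05), 5580 without overlap. Among tested genes 49.9% had no overlap (33.3% by chance). The median of all genes was 0.165 (log2), and it moved by -0.124 with DESeq2 size factors and by -0.172 with the length offset. Fitting only these groups called 219. Left out 1 at a time, libraries gave 10273 without Epcam-positive replicate 2 and 3829 without fetal TEC replicate 2. Of the calls 53.9% were higher, but 49.8% with DESeq2 size factors, 48.4% with the length offset, 21% with only these groups and 42.7% without Epcam-positive replicate 1 (3600 higher and 4840 lower). Cemip stood at least 759-fold higher without Epcam-positive replicate 1.

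**Figure D4:**
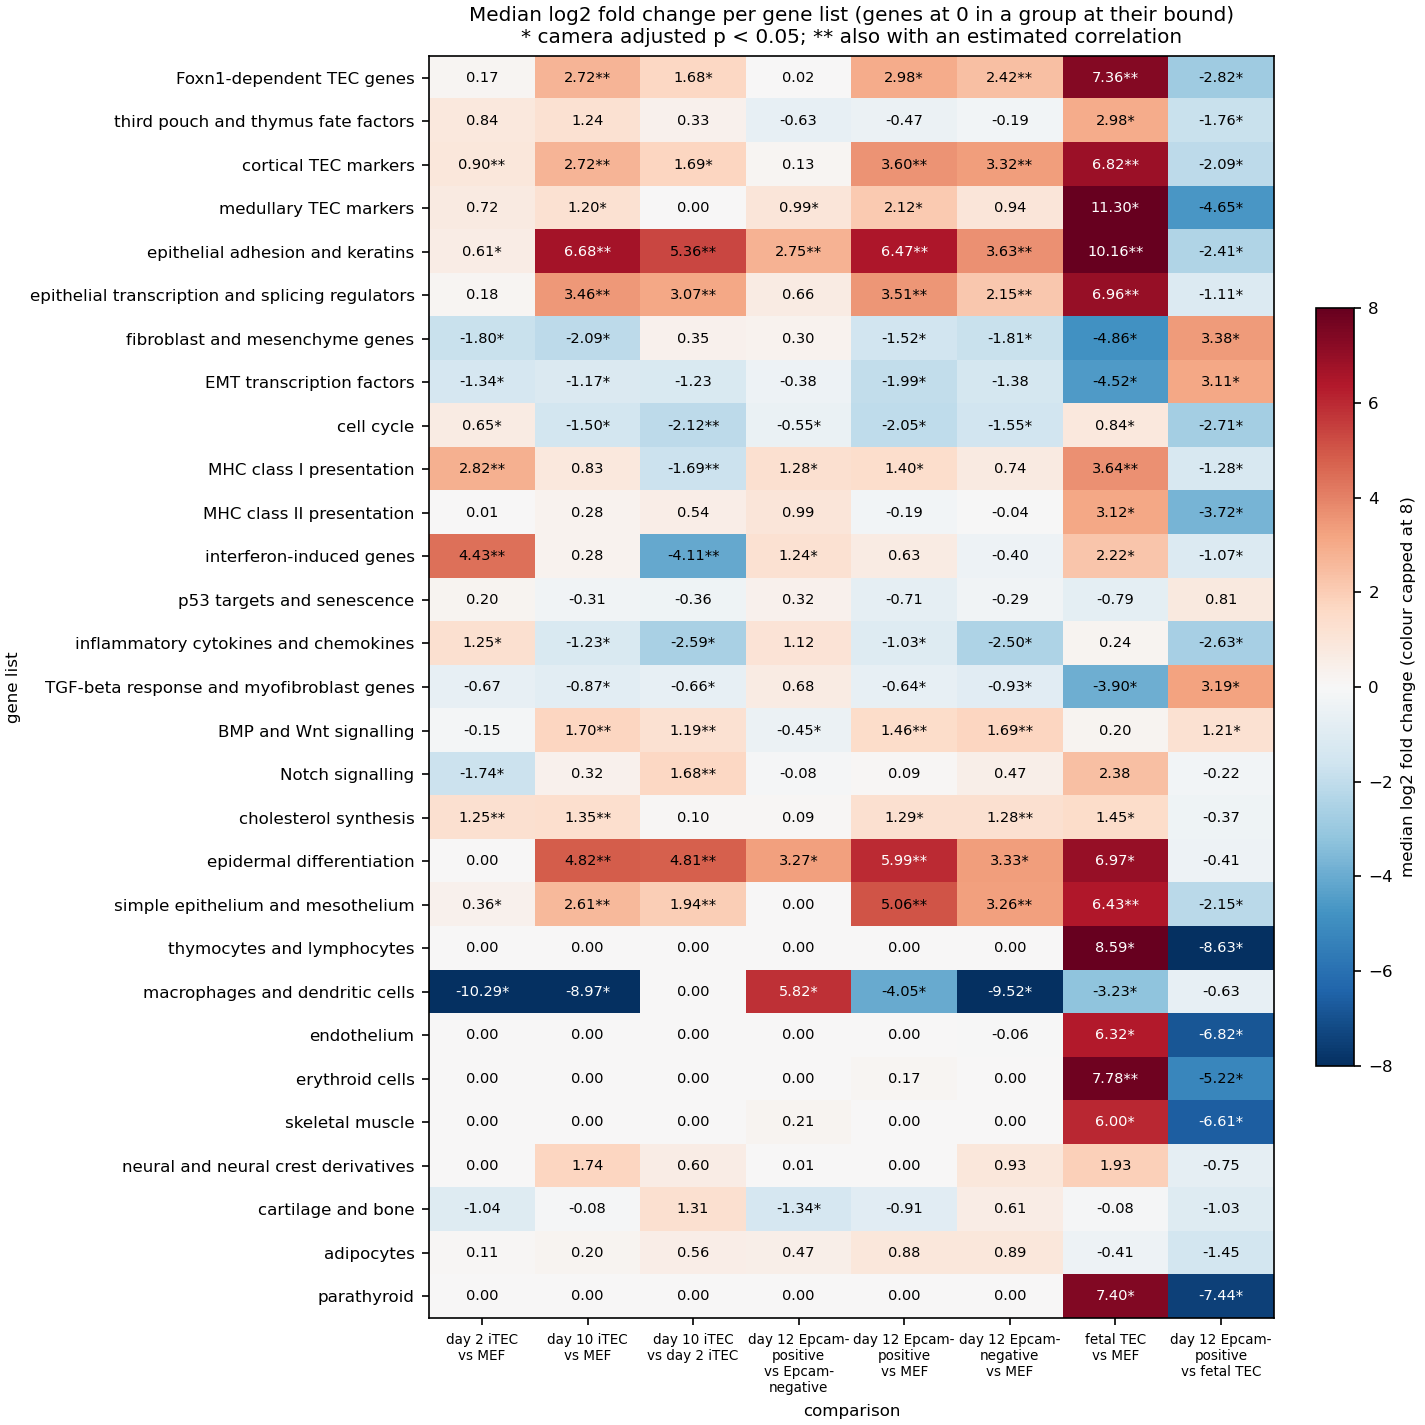
Median log2 change of each gene list (columns: comparisons, rows: lists), with genes at 0 set at their bound. Interferon-induced genes go from 4.43 at day 2 against MEF to -4.11 at day 10 against day 2.

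Whether the sort and the time course move toward fetal TEC was asked with pairs of comparisons that share no library. For the sort they share other differences: Epcam-positive replicate 2 and fetal TEC are length-skewed, and MEF and Epcam-negative libraries lack Y-linked genes that the others have, so overlap above chance can come from these as well. Of the genes called between fetal TEC and MEF, 26 were also higher in Epcam-positive than in Epcam-negative cells (12.9 by chance), 3 were lower in both (0.8), and 0 and 8 went opposite ways (0.9 and 10.8). Across the 9831 genes called between the controls, log2 changes correlated with r = 0.286, though genes are not independent replicates. The shared count of 29 (13.7 by chance) was 6804 without Epcam-positive replicate 1 (3341.3 by chance) and 203 without replicate 2 (185.1 by chance, r = 0.018). It lay between 0 and 10 without any 1 of the other libraries. From day 2 to day 10, 750 genes were higher in both comparisons (441.9 by chance) and 176 lower in both (197.1), 270 were higher in fetal TEC and lower at day 10 (236.5) and 219 the reverse (368.1), with r = 0.312. Shared falls lay under chance, which ignores the spread both tests share. Shared genes were 926 (638.9 by chance). They were 514, 514 and 520 without day 10 replicates 1, 2 and 3 (305.2, 307.4 and 307.2 by chance), and 2722 and 2717 without Epcam-positive replicates 1 and 2 (2063.8 and 2053.7 by chance).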

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

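Settings chosen after seeing the data were the 10 libraries without length skew, a length trend per library as an offset, and day 10 replicates 1 and 2 summed. In all, 26 alternatives were run, and the cause of a difference between settings was not tested. In the order day 2 against MEF, day 10 against MEF, day 10 against day 2, Epcam-positive against Epcam-negative, Epcam-positive against MEF and Epcam-negative against MEF, the edgeR counts of 938, 2720, 2151, 44, 3455 and 2025 genes became 2205, 4222, 3606, 1737, 6171 and 3642 with the DESeq2 Wald test. With only the compared groups they became 2949, 7959, 10927, 0, 0 and 4996, and 219 in place of 6052 for Epcam-positive against fetal TEC. For both zeros 349 and 1795 genes stood at unadjusted p under 0.05. With a fold minimum they became 484, 1539, 1163, 5, 1444 and 1129, and 3862 for Epcam-positive against fetal TEC. With the 10 libraries without length skew they became 6438, 9231, 8373, 1651, 6572 and 8671. With day 10 replicates summed, the first 5 became 576, 1455, 1133, 1 and 2142. Epcam-positive against Epcam-negative had 7 genes with library size alone, 24 with no filter and 74 with the length offset. Counts for fetal TEC against MEF stayed within 1.5 times of 9831 under these settings. Of the gene list tests, 121 passed, 42 with an estimated correlation and 134 by fry. The genes shared by fetal TEC against MEF and the sort (29) became 19 with DESeq2 size factors and 1149 with the DESeq2 Wald test. Those shared with day 10 against day 2 (926) became 1555 with the Wald test.

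Leaving out 1 library at a time gave 299 to 3718, 1028 to 6650, 564 to 5792, 0 to 9545, 669 to 10819 and 719 to 5897 genes in the same order, 5507 to 12611 for fetal TEC against MEF and 3829 to 10273 for Epcam-positive against fetal TEC. List calls went from 108 to 123, and the shared genes from 0 to 6804 for the sort and from 258 to 2722 for day 10 against day 2. A lone sample left in a group was assumed to vary like the other groups.

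With the replicate number as a block, the counts in that order were 391, 1040, 831, 1, 1036 and 915, and 3576 for Epcam-positive against fetal TEC. The shared genes were 1 and 397, 114 of the gene list tests passed, and 7913 genes were called for fetal TEC against MEF. Same-numbered samples deviated with r of -0.22 to 0.18 over 15 pairs of groups (4 above 0.1), but wide replicate spread could hide pairing.

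Directions turned in 8 cases, 7 of genes and 1 of a list under another kind of test. Apcdd1 had a log2 change of 0.005 between the sorted fractions (adjusted p = 1) and Kitl of 0.99 between fetal TEC and MEF (adjusted p = 0.00632) with the length offset. Between the sorted fractions Col1a1 had -3.28 and Thy1 -2.10 without Epcam-positive replicate 1, the lowest with 1 library left out (highest 1.23 and 2.72). Against fetal TEC, Vim had -0.94 and Thy1 -0.40 without Epcam-positive replicate 1 (highest 2.24 and 4.42), and Ccl25 -1.64 without replicate 2 (highest 1.93). The BMP and Wnt list of fetal TEC against MEF had adjusted p = 0.0304 upward by fry. Over the 438 gene and comparison pairs, 9471 results stayed the same, 748 were weaker and 153 stronger. Over the 232 list and comparison pairs these were 4342, 171 and 68. Changes of sign past no threshold (101) were counted as the same. Most simulated 4-fold changes were missed.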

Other observations

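The tests of fetal TEC mixed in, of another way of making libraries, of MEF control RNA carried over, of Foxn1 as the only driver and of immune cells at day 2 were chosen only after the result was seen, as were the genes and families described next. Hox genes kept the cultures apart from fetal TEC. Of 37 tested, 2 were higher and 26 lower in fetal TEC than in MEF, with a median log2 change of -5.97, and 30 were higher and 2 lower in Epcam-positive cells than in fetal TEC (median 7.79). At 1 CPM or more stood 24 to 34 of 39 Hox genes in the culture libraries and 5 or 6 in fetal TEC. Hoxa9, a gene of posterior and limb mesenchyme, went from 6.04 ± 1.92 CPM in MEF to 28.4 ± 2.9 CPM at day 10 and was at 0 in fetal TEC. At day 10, 9 Hox genes were above MEF and 0 below by edgeR.

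Hair genes followed. Of 11 keratin-associated genes tested, 9 rose and 0 fell at day 10 against MEF, and 8 rose in Epcam-positive cells against MEF. Single regulators known from hair or bone had other levels as well, given as CPM in MEF and at day 10: Dlx3 from 0.181 to 48.4, Msx2 from 1.92 to 39.7 and Sp7 from 0.167 to 65.4, while of 18 cartilage and bone genes 5 rose and 3 fell (median log2 change -0.08, mean 1.02, test upward, adjusted p = 0.935). The Wnt feedback genes Axin2 and Nkd2 went from 7.89 to 119.5 and from 8.73 to 183, and stood at 0.219 and 29.2 CPM in fetal TEC. Lef1, also of this pathway, went from 0.897 to 14.6 and stood at 36.7 ± 22.3 CPM in fetal TEC. Genes of other organs stood in fetal TEC beside Aire (142 CPM) and Fezf2 (164 CPM): Csn2 of milk at 322, Ckm of muscle at 159, Chga of endocrine cells at 136.5 and Sftpc of lung at 105 CPM.

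Epcam-positive replicate 2 stood apart from replicate 1. After the length trend was removed, the SD of the log2 ratio of both libraries was 2.53 (2.81 before), above the highest of the other pairs (1.35), which argues against length as the whole cause. Prss16, Cd74 and H2-Ab1 stood at a median of 0.192% of their fetal TEC level, which argues against fetal TEC RNA or a fetal TEC library under that label. Its longest minus shortest length bin of -3.72 lies beside fetal TEC (-3.31 and -2.88) and outside the other cultures (-0.12 to 0.62), but these bins are the skew that raised the question and so decide nothing about its origin. Another way of making the library, as for fetal TEC, and degraded RNA both stay open. A biological difference between the sorted cultures stays open and was not tested.

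Macrophage genes stood higher in Epcam-positive replicate 1 than in other iTEC libraries. Xist, at 0.0681% of its MEF level where macrophage genes had a median of 9.43%, reached only 0.723% of that share (1.27 CPM where 175 would be needed), which argues against RNA of the MEF control cultures carried over. Of the 16 macrophage genes with 5 CPM or more in MEF, 14 (87.5%) were over 4-fold above the Epcam-negative mean, which restates the pattern and decides nothing about its origin. Against day 10 and Epcam-negative libraries, fibroblast genes were higher in it too: Vim stood at 1093 CPM (152 to 273), Thy1 at 156 (18.6 to 68.99) and Col1a1 at 16630 (6909 to 9155). Unconverted cells or RNA of a male culture, which would bring no Xist, and macrophages among the sorted cells all stay open. Epcam in replicate 1 was below day 10. A macrophage-like state of sorted cells was not tested.

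Interferon-induced and inflammatory genes were high at day 2. Their median log2 change against MEF over 51 genes was 3.58 at day 2 and -0.04 at day 10 with Foxn1 still high, which argues against Foxn1 as the only driver at all times. Tested macrophage and lymphocyte genes summed, with TMM factors, to 41.9 CPM at day 2 and 3730 in MEF (1.12%). This argues against immune cells after sorting, not before. The delivery of DNA by nucleofection and an early effect of Foxn1 cannot be told apart, since 0 libraries were nucleofected without Cre. Either could raise these genes.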
